A study of Bos taurus with 30 samples.

How the data were processed

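Messenger RNA was sequenced from liver samples of 30 crossbred heifer calves, 15 fed a high and 15 a moderate plane of nutrition. The labels state a polyA selection, a strand-preserving Illumina TruSeq library kit and an RNeasy Plus Universal extraction. The extraction text names hypothalamus as the source, whereas the title, source and tissue labels of all 30 samples say liver. The tissue was not checked by marker genes, because no identifier could be given a gene name, so liver stands here for what those labels say. Diet was taken from the diet label of each sample. Replicates were numbered in accession order, so a number only names a library and pairs nothing. The labels give no batch, date or pen, and each sample has its own animal tag.

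Per the submitters' processing notes, FastQC 0.11.8, cutadapt 2.6, STAR 2.6.1, R 3.4 and edgeR 3.5 were used and the genome build was UMD3.1. The counting tool, its strand setting and the annotation release are not given in the sources used here. The data came as 1 table of 24596 genes by 30 libraries, with 0 columns from outside the series. The table is titled as counts, but the deposited values are a scaled signal, namely gene counts divided by each library's scaled total, per 1000000 (scaled CPM). Column sums ran from 888410 to 1100850 with a geometric mean of 1000000. In every column all values above 0 (471204 in total) were whole multiples of 1 step within a tolerance of 0.001, so the whole reads behind 100% of them were recovered. Trimmed-mean (TMM) factors recomputed from those reads differed from the factors in the deposited values by a relative 2.25e-11 at most. The file held scaled values, not raw counts. After it was seen, limma on log2 values took the place of edgeR's quasi-likelihood test, the main test planned before the data were examined. The recovered reads did allow the planned test, which was run on them as an alternative. All 24596 rows carried a gene identifier, so no unassigned reads had to be set aside.

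Recovered library totals ran from 11528471 to 17906182 reads (median 14165610), and 1 read was worth 0.0554 to 0.0955 scaled CPM. Between 15402 and 16021 genes had at least 1 read per library. The 435 pairs of libraries were compared by chi-square over the tested genes. The closest pair gave 18.1 per degree of freedom, far above sampling noise, so no library was counted as a duplicate. All libraries were used.

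Genes were tested if edgeR's filterByExpr kept them on the recovered reads (a minimum of 10 reads, scaled to the median library, in about as many libraries as a group holds), which left 12913 genes. The main test was limma (version 3.58.1) with a mean-variance trend on log2(scaled CPM + 0.5), High minus Moderate, no covariates, and a Benjamini-Hochberg adjusted p below 0.05. The pseudocount was set after the table was seen. A fold change on this scale understates the change of low genes. The share of genes with any difference was estimated with limma's propTrueNull (convex decreasing density). The script was tested on simulated counts for the High against Moderate comparison, drawn for the 12913 genes with the estimated dispersions. With 50 changed genes per size, limma recovered 30% of 1.25-fold, 82% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes, with 9 false calls. Far fewer genes changed there than were called in the data, and genes were drawn independently. These shares are therefore not the sensitivity of the real comparison.

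Library measures (total reads, genes detected, share of the 10 most abundant genes, principal components 1 and 2 of the 500 most variable genes, distance to the group centroid) were compared by a two-sided permutation test with 100000 resamples (scipy 1.17.1), with Benjamini-Hochberg adjustment over 6 measures. A planned share of mitochondrially encoded reads was not computed because it needs gene names. Each library was also left out in turn and placed between the group centroids of the genes called without it.

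Gene names were a limit. The table gives Ensembl identifiers only, the table of ARS-UCD2.0 genes used here matched 0 of them, and no annotation of UMD3.1 was used. Genes are therefore reported by identifier, without symbol or position, and the 39 gene lists fixed before the data were examined, with their set tests, were not run. The rule for named genes (past the threshold, mean of at least 1 scaled CPM in a group, at least 12 of 15 High libraries on the called side of the Moderate median, ranked by fold change) was applied without its symbol criterion and stopped at 2 genes in each direction. The genes the rule would always have named by symbol could not be looked up.

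Alternatives fixed beforehand were RLE and upper-quartile scaling, 2 other filters, DESeq2 1.42.0, voom with quality weights, edgeR's likelihood ratio test, 2 other thresholds, 1 surrogate variable (sva 3.50.0), thinning to the smallest library, and each library left out in turn. The planned main test, edgeR 4.0.16's quasi-likelihood test, was run on recovered reads as an alternative. Added after the data were seen were DESeq2 on the genes the limma test used, pseudocounts of 0.1 and 1, and no scaling factor. Leaving out the 3 libraries least correlated with the rest was also added then. Other splits of the libraries were drawn 100 times with the real one included, and 100 sets of 3 Moderate libraries were left out in the same way.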

Results

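Transcriptomes of samples labelled as liver were measured in 30 Holstein-Friesian by Angus heifers at 21 weeks of age. From 2 weeks of age, 15 calves were fed a high and 15 a moderate plane of nutrition, with targets of 1.2 and 0.5 kg of daily gain. During the 8-week calf phase the High group was offered 1.5 kg of milk replacer a day in 10 litres, with concentrate always on offer. The Moderate group had 0.5 kg in 4 litres, and 1 kg of concentrate. In the 11-week phase after weaning both groups had hay to appetite, with concentrate unrestricted for High and held at 1 kg a day for Moderate. Each library came from 1 calf. High libraries held 13829700 reads ± 1582080 (SD, n = 15) and Moderate libraries 14337600 reads ± 1614690 (SD, n = 15). Of the 24596 genes listed, 18765 had at least 1 read and 12913 were abundant enough to test. The single comparison of the series was High against Moderate, and it asks how feeding level in early life alters hepatic gene expression.

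The livers separated by diet along their largest axis of variation. On principal component 1, which carried 22.2% of the variance of the 500 most variable genes, High libraries averaged 10.5 ± 3.05 (SD, n = 15) and Moderate libraries -10.5 ± 5.61 (SD, n = 15). The groups did not overlap, with a lowest High score of 5.97 and a highest Moderate score of -2.41. The permutation p was 2e-05, the smallest that 100000 resamples can give (adjusted p = 0.00012 over 6 measures). Component 2 (11.9% of variance) differed by 4.43 between group means, less than its spread within either group (permutation test, adjusted p = 0.263). When each library was left out and placed on the line between the Moderate centroid (0) and the High centroid (1) of the genes called without it, 30 of 30 libraries fell nearer to their own group. High livers ranged from 0.698 to 1.06 on that line and Moderate livers from -0.250 to 0.318.

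**Figure D1:**
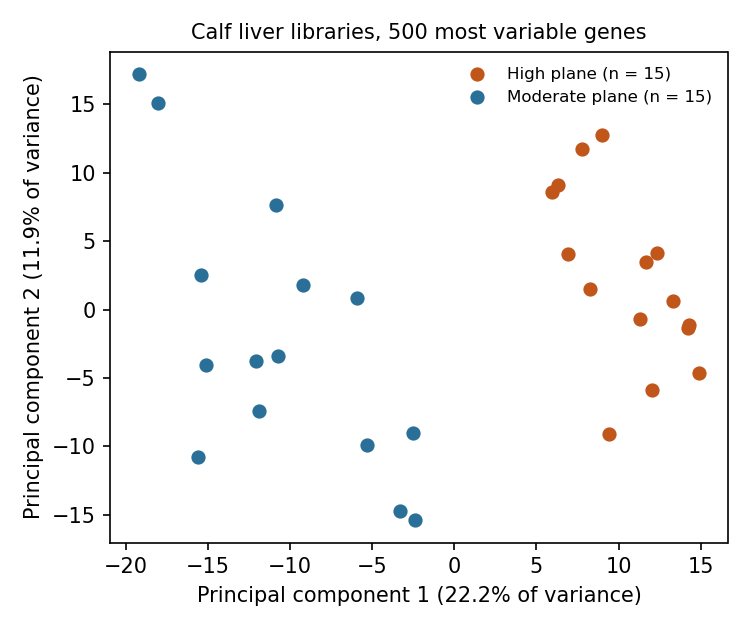
Scores of the 30 liver libraries on principal components 1 (x axis, 22.2% of variance) and 2 (y axis, 11.9%) of log2 scaled CPM, 1 point per calf, coloured by plane of nutrition. The High libraries lie at 5.97 or above on component 1 and the Moderate libraries at -2.41 or below.

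Liver expression of 1551 genes differed between the diets, out of 12913 tested (limma, adjusted p below 0.05). Of these, 816 rose and 735 fell in High livers relative to Moderate livers. Most of the changes were small. The median fold was 1.33, with quartiles of 1.22 and 1.54, and 1106 of the 1551 genes (71.3%) moved by less than 1.5-fold. At 2-fold or more, 76 genes rose and 66 fell, and at 4-fold or more 9 rose and 13 fell. These counts depended on the settings. At 2-fold or more DESeq2 gave 171 higher and 136 lower when run on 18765 genes, 2912 of which got no adjusted p. On the 12913 genes tested here it gave 113 and 94, and the planned edgeR quasi-likelihood test 111 and 92. In 26 genes the High and Moderate values did not overlap in any library, 14 of them higher and 12 lower in High, where chance gives 0.000166 genes at 15 against 15. From the distribution of p-values, an estimated 36.8% of tested genes differed to some degree. This point estimate has no interval and takes no account of genes that vary together.

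The balance of higher against lower genes rested on the scaling of the libraries. With the deposited TMM factors, 52.6% of changed genes were higher in High, with RLE factors 53.3% and with upper-quartile factors 54.9%. With plain CPM, which moved the median of all genes by -0.05 on the log2 scale, 630 were higher and 1097 lower (36.5% higher).

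**Figure D2:**
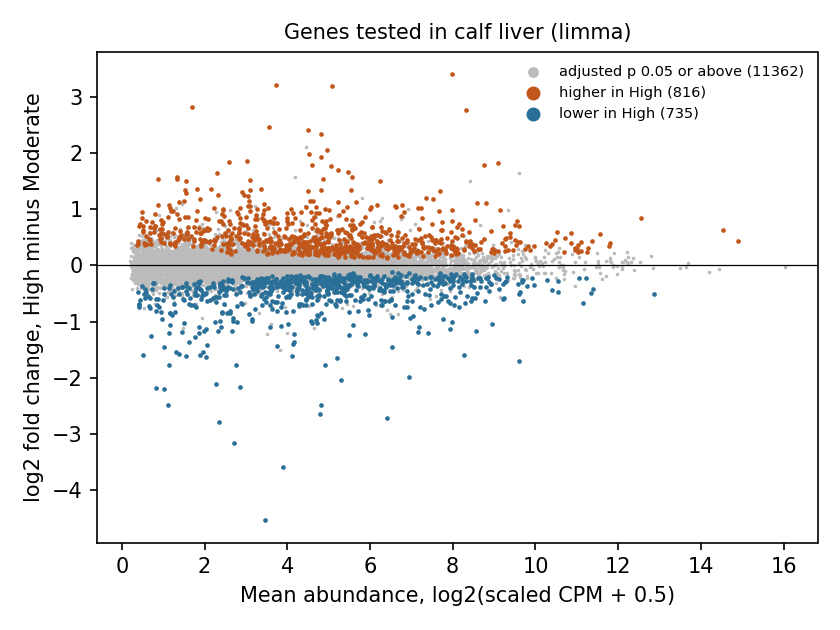
Log2 fold change, High minus Moderate (y axis), against mean abundance on a log2(scaled CPM + 0.5) scale (x axis) for the 12913 genes tested, 1 point per gene. The 816 higher and 735 lower genes (limma, adjusted p below 0.05) are coloured and lie on both sides of 0 across the range of abundance.

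Abundant liver transcripts were called more often than rare ones, a difference that was described and not tested. Among 121 genes with a mean above 1000 scaled CPM, 26 rose and 11 fell in High (30.6% called), and among 1085 genes between 100 and 1000, 160 rose and 148 fell (28.4%). Between 10 and 100, 415 of 6632 genes rose and 387 fell (12.1%). Between 1 and 10, 201 of 4710 rose and 179 fell (8.07%), and below 1, 14 of 365 rose and 10 fell (6.58%). The median standard error of the log2 fold change, from the lowest class to the highest, was 0.15, 0.12, 0.08, 0.08 and 0.09. Called genes below 1 scaled CPM had a median absolute log2 fold change of 0.61, against 0.39 for those above 1000.

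The changed genes accounted for a sizeable part of the liver's polyadenylated RNA. The 816 genes higher in High held 19.5% ± 0.823 (SD, n = 15) of all reads in High livers and 14.4% ± 0.713 (SD, n = 15) in Moderate livers. The lowest High library (18.4%) lay above the highest Moderate library (15.6%). Among them, the 26 genes above 1000 scaled CPM rose from 9.08% ± 0.578 of reads in Moderate to 12.2% ± 0.759 in High (SD, n = 15 each). The 735 lower genes held 7.14% ± 0.253 in High and 9.96% ± 0.548 in Moderate (SD, n = 15 each). These sets were chosen on the same libraries, so the sizes of these differences are not independent evidence. The genes that changed 2-fold or more held little RNA: the higher ones made up 0.683% of reads in High and 0.249% in Moderate, and the lower ones 0.207% and 0.562%.

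By limma with a pseudocount of 0.5, the largest rise among the called genes was that of ENSBTAG00000016472, at 457 ± 138 scaled CPM in High and 48.5 ± 30.6 in Moderate (SD, n = 15 each). Its log2 fold change was 3.41 (SE 0.27; limma, adjusted p = 5.21e-11), and its lowest High library (156) exceeded its highest Moderate library (117). ENSBTAG00000011666 rose from 4.01 ± 7.20 to 21.4 ± 7.43 scaled CPM (log2 fold change 3.22, SE 0.41; limma, adjusted p = 1.01e-06). Its groups overlapped through Moderate replicate 7 alone, at 28.4 scaled CPM. Without that library the Moderate mean was 2.27 ± 2.58 (SD, n = 14), the highest Moderate value was 7.88, below the lowest High value of 12.3, and the log2 fold change was 3.48, above the 3.32 of ENSBTAG00000016472. The order of these genes also turned with voom (3.96 for ENSBTAG00000011666 and 3.35 for ENSBTAG00000016472) and with a pseudocount of 0.1 (3.76 and 3.43), while edgeR's quasi-likelihood test kept it (2.40 and 3.23). The files do not pair these identifiers with gene names.

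By the same measure, the largest fall was that of ENSBTAG00000011624, which was nearly silent in High livers. It had 13 reads in total in the 15 High libraries, 9 of which had none, and 4675 reads in the Moderate libraries. Its mean was 0.0565 ± 0.0805 scaled CPM in High and 21.0 ± 21.1 in Moderate (SD, n = 15 each), with a log2 fold change of -4.54 (SE 0.42; limma, adjusted p = 2.40e-09). Its fold change depended on the scale, from -3.71 with a pseudocount of 1 to -8.45 with DESeq2, and the ratio of group means, Moderate over High, was 372. Moderate calves ranged from 0.374 to 81.3. ENSBTAG00000002559 had the smallest p of all genes tested. It fell from 27.2 ± 17.2 scaled CPM in Moderate to 1.53 ± 0.633 in High (log2 fold change -3.58, SE 0.22; limma, adjusted p = 8.54e-13). Its highest High library (3.55) lay below its lowest Moderate library (8.91).

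**Figure D3:**
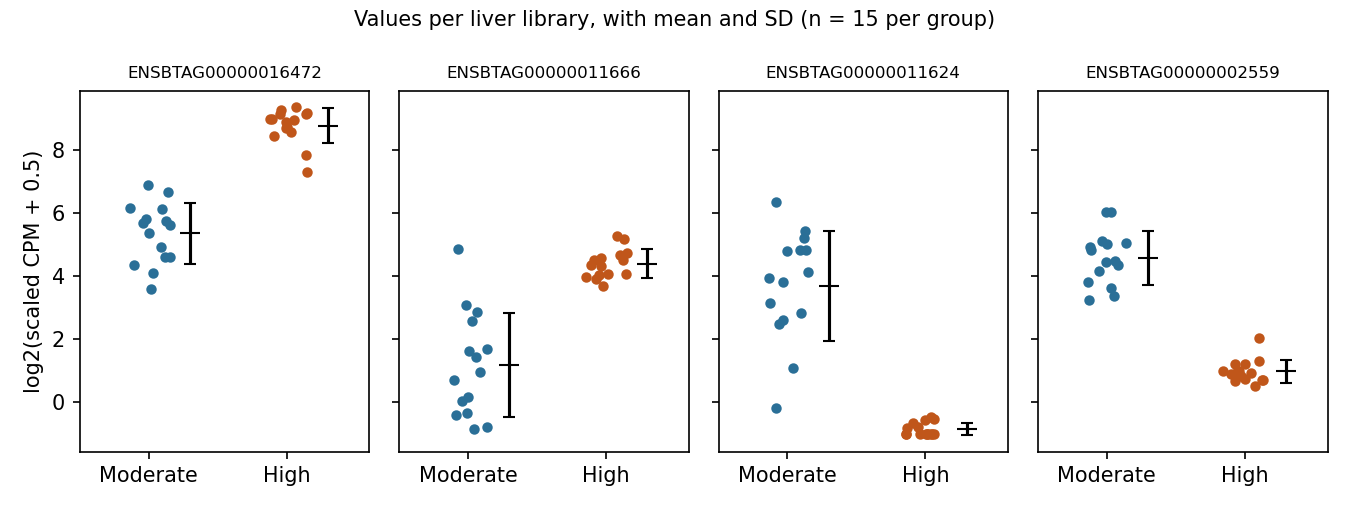
Values of the 4 named genes per liver library as log2(scaled CPM + 0.5) on a shared y axis, 1 point per calf, with black marks for the mean and SD of 15 libraries. The High and Moderate points are separate for ENSBTAG00000016472, ENSBTAG00000011624 and ENSBTAG00000002559 and overlap for ENSBTAG00000011666 through 1 Moderate library.

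Apart from component 1, none of the 6 library measures passed the test. Total reads differed by less than their spread within groups (permutation test, adjusted p = 0.469), as did the number of genes detected, 15669 ± 129 in High and 15745 ± 165 in Moderate (SD, n = 15 each; permutation test, adjusted p = 0.263). The 10 most abundant genes took 21.9% ± 1.43 of reads in High and 21.1% ± 1.06 in Moderate (SD, n = 15 each; permutation test, adjusted p = 0.194). The distance of a library to its group's centroid was 21.4 ± 1.19 in High and 21.7 ± 2.61 in Moderate (SD, n = 15 each; permutation test, adjusted p = 0.698). The 3 libraries least correlated with the mean of the others (0.976 to 0.978) were Moderate replicates 6, 5 and 4. Without them 1436 genes were called, 724 higher and 712 lower in High. The labels name no batch, so no value within batches could be given.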

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

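The quasi-likelihood test, DESeq2 on the same genes, other pseudocounts, plain CPM and leaving out 3 libraries were chosen after the data were seen. The count of changed genes stayed within 1.5 times of 1551 under the alternatives tried, apart from the stricter threshold that also asked for 1.5-fold, which by construction left 445 genes, 255 higher and 190 lower in High. Without that threshold, and with other sets of 3 Moderate libraries set aside, counts ran from 1389 (without Moderate replicate 11) to 2119 (adjusted p below 0.1). Leaving out those other sets of 3 gave 1149 to 1860 genes. DESeq2 called 1855 (1789 on the same genes), voom with quality weights 1665, and edgeR's quasi-likelihood and likelihood ratio tests 1600 and 1702 on the recovered reads. The surrogate variable gave 1669, no filter 1508 and thinned libraries 1544. Apart from those other sets of 3, where signs were not examined, none of these settings turned the sign of a called gene. That was close to fixed in advance, since the genes were selected as called in all or most of the same libraries. Without the 1.5-fold threshold, between 81.2% (3 least typical libraries left out) and 100% of the 1551 genes were called again in the same direction. The 100% belongs to the looser threshold, where it was fixed in advance. Other sets of 3 Moderate libraries left out kept 71.8% to 91.5%. Leaving out 1 library at a time gave 1389 to 1638 genes, 750 to 871 higher and 639 to 778 lower. Plain CPM moved the higher share to 36.5%, while RLE (53.3%) and upper-quartile scaling (54.9%) left it close to 52.6%. At 2-fold or more DESeq2 gave 171 higher and 136 lower against 76 and 66, but when run on 18765 genes, 2912 of which got no adjusted p. On the 12913 genes of the limma test it gave 113 and 94, and edgeR's quasi-likelihood test 111 and 92. The 4 named genes kept their direction and call wherever they were tested. Principal component 1 separated the diets with 1000 genes as with 500 (permutation p = 2e-05). Simulated data at this depth and n gave back 82% of 1.5-fold changes and 30% of the smallest changes tried. They held far fewer changed genes than the data, so these shares are not the sensitivity of the real comparison. The alternatives for gene lists were not run, because no list could be matched to the identifiers.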

Other observations

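Chosen after their results were seen were the tests of the on and off states, the comparison of variances and the intervals used to judge the percent of calls kept and the module correlations; the definitions of the on and off genes and of the modules were also set with the data in view. The comparison of depth between on and off libraries and that with other sets of 3 libraries were added late, with their limits set before their results were seen.

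A few genes were fully on in the livers of some calves and off in others. A first definition (3 or more libraries at 5 scaled CPM or above and 3 or more below 0.3) gave 44 genes. A stricter one with every library below 1 or at 3 and above gave the 7 described here. The stricter rule left out ENSBTAG00000011624, which met the first one and was at 0.218 scaled CPM or below in every High library. Moderate replicate 1 alone, at 1.62, kept that gene out. The 7 genes therefore do not stand for all genes that were on or off by diet. ENSBTAG00000021077 was on in 2 of 15 High and 8 of 15 Moderate calves, at a median of 21.5 scaled CPM, with 0 reads in the others. ENSBTAG00000038128 was on in 13 calves, which included all 10 that expressed ENSBTAG00000021077 (27 of 30 libraries in the same state for both; Fisher's exact test, adjusted p = 0.0002 over 21 pairs). Both were singled out after their values were seen, and the files pair neither with a gene name.

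Counting noise was kept out by the definition itself: at the on level the shallowest off library would have held 88.2 to 258 reads, against medians of 0 to 7 observed in off libraries. Another link with library depth stays open. An off library had more reads than the median on library of the same gene in 36.0% of 125 pairs. The 95% interval over resampled libraries, 18.5 to 49.6%, reaches below the limits of 20% and 30% set beforehand. In most pairs the off library thus had fewer reads. High libraries averaged slightly fewer reads than Moderate libraries, so this lean was not separated from diet. For these 7 genes plane of nutrition alone was excluded, since 7 of the 7 had calves in both states in both groups. A partial link with plane of nutrition stays open. By Fisher's exact test 0% of the genes passed after adjustment, and 0 had an unadjusted p below 0.05 (smallest p = 0.0502 for ENSBTAG00000021077). The 95% bound on the share of genes that pass this test reaches 41.0%. It does not bound the share linked to diet, since even 2 High against 8 Moderate calves on did not pass. The bound takes the 7 genes as independent, although ENSBTAG00000021077 and ENSBTAG00000038128 shared a state in 27 of 30 libraries. Of the 7 genes, 6 were on in fewer High than Moderate calves and 1 was tied, a tally that was not tested. An inherited difference between calves, or an allele whose reads do not match the reference, is a candidate explanation, and neither was tested.

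Genes that varied together between calves were grouped among the 4000 tested genes chosen for the most variance within groups, of which 586 (14.7%) were called by diet. They gave 20 modules of at least 20 genes, with 122 of 1128 genes called (10.8%). The 3 largest held 12 called genes of 467 (2.57%), some other modules held larger shares, and the differences between modules were not tested. By permutation test on the module score 0 of 20 modules passed after adjustment for a difference between diets. At an unadjusted p below 0.05 there was 1, a module of 48 genes of which 20 fell and 1 rose in High. Its score difference was -0.72 (permutation test, p = 0.0092, adjusted p = 0.184), with 14 of 15 High libraries below the Moderate median. Building modules on variation within groups keeps the spread of their scores large. That favours a null here, so 0 of 20 does not show modules free of diet.

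Library depth and complexity were tested as sources of the 3 largest modules, by correlation within groups over 30 libraries with total reads, genes detected and the share of the 10 most abundant genes. The largest Pearson r in size was 0.170 for the first module (rho -0.06), 0.227 for the second (rho -0.15), both with the top 10 share and negative, and 0.301 for the third, with total reads and negative (rho -0.29), with permutation p of 0.364, 0.243 and 0.112 for r and 0.741, 0.428 and 0.121 for rho. Without the 2 libraries farthest from the median these r were -0.168, -0.207 and -0.259, while the r of the first module with genes detected moved from 0.0672 to 0.331. Of 60 relations over all modules, 0 passed adjustment and 3 had an unadjusted p below 0.05. For the 3 modules every r was below 0.5 in size, the limit set beforehand for r itself. The upper 95% bounds, added after the results were seen, were 0.505, 0.548 and 0.601 and exceed 0.5. A moderate technical share therefore cannot be told apart from variation between animals.

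Several sources of the 1551 calls other than diet were tested: of 100 splits of the 30 libraries only 1, the real one, gave as many genes, and the highest of the others gave 39, so chance can be excluded at this share. Unequal read numbers were argued against, as 94.3% of the genes were called again in the same direction after thinning every library to the smallest. The groups differed little in depth to begin with, and thinning cannot show a difference in library quality that goes with depth. Without the 3 least typical libraries, all Moderate, 1436 genes were called and 81.2% of the 1551 were kept. That share met the limit set beforehand, which was at least 80% kept. A binomial 95% interval over genes (79.1 to 83.1%), added after the results were seen, includes 80%. It takes genes as independent and does not measure the spread over libraries, so this test stays undecided. The 292 lost genes kept their sign, which was likely from the start for genes selected as called. Their median absolute log2 fold change was 0.31 before and 0.27 after, with a median SE of 0.10 in both. That these 3 libraries carried more calls than other sets of 3 Moderate libraries was argued against, as 35 of 100 such sets, these included, kept as few. The other sets kept 71.8% to 91.5%, with a median of 83.8%. Pen, sampling order or any other factor shared by a diet group is not recorded in the labels and was not tested.

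Within-group variance was lower in High for 56.0% of genes, with a median log2 ratio of -0.13, and 35 of 100 splits gave a median as far from 0.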
